A study of Rattus norvegicus with 6 samples.

How the data were processed

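RNA came from tissue labelled prefrontal cortex, from 6 male F344 rats aged 18 months. Per the labels, 3 rats were given cranial osteopathic manipulation, a manual treatment of the head, over 7 days under 1.5 to 3% isoflurane, and the 3 untreated rats were anaesthetised as well. A coronal slab 1 mm thick was cut with a brain matrix. Each rat gave 1 library, and groups follow the treatment label: untreated replicates 1, 2 and 3, and manipulated replicates 4, 5 and 6. The labels give no batch, date or pairing.

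The deposited values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), as the authors made them with STAR 2.7.3a and Cufflinks (version not given) on the rat build Rnor_6.0, per the submitters' processing notes. Per the file headers, each of the 6 tables is a gene-level tracking table with an FPKM value, the lower and upper bound of its interval and a status. Each table also holds loci assembled in that library alone, which carry no gene name. Read totals, the annotation release, strandedness and RNA selection are not given in the sources used here. FPKM is scaled within a library, so a transcript that takes many fragments lowers all others. Where the assembly joined neighbouring genes in a row, their fragments could not be told apart. Without strand, reads of a gene and of a transcript on the opposite strand cannot be separated either.

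Rows were matched by gene symbol and the rows of a symbol at the same place were summed. Of 30076 symbols, 3254 shared a row with another gene in at least 1 library, 140 lay at several places, 32 were missing from a library and 7 had a failed estimate. These were left out, which kept 26682 symbols, and the 10676 with a mean of at least 1 FPKM over the 6 libraries were tested. Start positions were found to count from 0 and are given here counted from 1. Biotypes came from a RefSeq table of the assembly GRCr8, used for names and biotypes alone, and covered 84.5% of tested genes. Genes of the mitochondrial chromosome were not analysed here.

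Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no covariate, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Log2 fold changes are manipulated minus untreated on that scale, which understates the change of low genes. Gene lists, 39 in all, were fixed before the data were examined, and the 35 with at least 5 tested members were tested with camera at a preset correlation of 0.01. The camera test compares a list with all other tested genes. It was run again with an estimated correlation, and fry was run beside it, once for a shift of a list in a common direction and once for change in either direction. Single values per library were compared by an exact two-sided permutation test over the 10 splits of 6 libraries into 3 and 3, so that the smallest p it can give is 0.1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

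The genes named were set by a rule written before the data were examined. It takes every cholinergic transmission gene with a mean of at least 1 FPKM, the 10 largest increases and the 10 largest decreases past the adjusted p with ranges that do not overlap, and the 2 to 4 members with the smallest p of each called list and each cell type list. Genes with a clone or locus name were counted and not named. Any other gene named in the text was chosen after its values were seen.

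The test was checked on simulated data with 10676 genes and 3 libraries in each group. Of genes changed by 1 on the log2 scale 15.4% were recovered, and of genes changed by 2 it was 76.8%, with a mean of 8.2 false calls in each of 5 simulations. The camera test called 20 of 20 lists of 15 genes shifted by 1 and 2 of 20 lists that were not shifted.

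Because the tables hold no counts, depth was estimated from the width of the FPKM intervals of unnamed loci 400 to 800 bases long, taking the interval as 2 SDs of a Poisson count on each side. This estimate is called the implied fragment number. It can be compared between libraries and is not a read total.

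Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the variance model, weights per library, the genes kept, the list test and leaving out each library. Those added after the data were seen kept the rows that name several genes, limited the change in row span between libraries to 1.5 times, left out genes at 0 throughout a group, and used median-ratio scaling for list levels. Their effect is given in the closing section.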

Results

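The study asked whether cranial manipulation of aged rats goes with a change in the genes of the cholinergic pathway in the prefrontal cortex. It compared 3 manipulated with 3 untreated rats, with 1 RNA library from each. The implied fragment number was 3.84e+07 ± 2.20e+06 (SD, n = 3) in untreated and 3.78e+07 ± 5.34e+06 in manipulated libraries, with an exact permutation p of 0.8. Between 10264 and 10928 genes reached 1 FPKM in an untreated library and between 9264 and 10159 in a manipulated one, with an exact permutation p of 0.1, the smallest that 3 against 3 allows. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.865 to 0.887 within the untreated group, 0.885 to 0.898 within the manipulated group and 0.830 to 0.893 between groups.

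Most tested genes had lower FPKM in manipulated rats. The median log2 fold change over 10676 genes was -0.36, and 87.0% of genes lay below 0. The shift did not separate the libraries. Tested genes had a median of 5.50, 3.98 and 5.17 FPKM in the untreated and 4.01, 4.08 and 2.76 FPKM in the manipulated libraries. The exact permutation p of these medians was 0.3. With median-ratio scaling between libraries the median log2 fold change was -0.0037, so that a change is best read against the shift of -0.36.

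Among cholinergic genes, the nicotinic receptor subunits Chrna4 and Chrnb2 fell in manipulated rats when p was adjusted over the list alone. Their products join in the main high-affinity nicotinic receptor of the brain. Chrna4 (chromosome 3, 176527516 to 176548208, Rnor_6.0) had 10.3 ± 0.912 FPKM (SD, n = 3) in untreated and 3.97 ± 0.485 FPKM in manipulated rats, a log2 fold change of -1.18 (SE 0.22), with a limma adjusted p of 0.00395 over the list alone and 0.0839 over all genes. Chrnb2 (chromosome 2, 189088570 to 189096785) had 11.6 ± 2.29 and 5.63 ± 1.31 FPKM, a log2 fold change of -0.93 (SE 0.26), with adjusted p of 0.0328 and 0.271. With median-ratio scaling the log2 fold changes were -0.79 and -0.53, and over the list alone Chrna4 passed, with an adjusted p of 0.00954, while the call of Chrnb2 ended, at 0.0770. Neither passed over all genes, and 0 of the 11 tested genes of the list did by limma, although 2 had an unadjusted p under 0.05. Of 21 other settings, Chrna4 passed over all genes in 4, with a robust variance prior, with weights per library, over genes above 0 in all 6 libraries and over protein-coding genes, with 0.00563 the lowest adjusted p, and Chrnb2 in 1, with weights per library, at 0.0481.

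The other 9 tested genes of the list passed neither test. The muscarinic receptor gene Chrm1 had 11.4 ± 4.33 FPKM in untreated and 10.1 ± 2.11 FPKM in manipulated rats (SD, n = 3). Chrm2 had 1.31 ± 0.138 and 1.70 ± 0.456 FPKM, and Chrm4 1.31 ± 0.312 and 2.45 ± 1.37 FPKM. Chrna7, which forms a nicotinic receptor of its own, had 2.03 ± 0.739 and 3.95 ± 2.35 FPKM. Lynx1 and Ly6h, which encode small proteins that bind nicotinic receptors, had 32.6 ± 3.07 and 65.5 ± 4.17 FPKM in untreated rats, and 24.8 ± 6.19 and 62.2 ± 7.82 FPKM in manipulated rats. Ric3, a chaperone of nicotinic receptors, had 3.29 ± 1.93 and 2.41 ± 0.978 FPKM, Prima1, the membrane anchor of acetylcholinesterase, 2.04 ± 0.449 and 1.87 ± 0.473 FPKM, and the choline transporter-like Slc44a1 16.6 ± 2.12 and 13.1 ± 3.66 FPKM. As a list, cholinergic transmission had a median log2 fold change of -0.12 and a mean of -0.19, against -0.36 for all genes, and the camera adjusted p was 0.435 (0.999 with an estimated correlation). The fry test for change in either direction gave an adjusted p of 0.0103, and its test for a common direction gave 0.368. The test for either direction passed 7 of the 35 lists, the others being glutamatergic neurons (0.000656), interneurons (0.000688), monoamine receptors (0.000284), olfactory bulb (0.0183), thalamic and hypothalamic neurons (0.000284) and immediate early genes (0.0223). Of the 11 genes 8 were lower as deposited, and 9 were higher with median-ratio scaling.

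Genes of acetylcholine synthesis and transport lay below the filter, and 16 of the 30 list genes did so. They were chosen for naming after their values were seen. Chat, the enzyme that makes acetylcholine (chromosome 16, 8577840 to 8686131), had 0.302 ± 0.147 FPKM in untreated and 0.976 ± 0.370 FPKM in manipulated rats (SD, n = 3), a ratio of 3.23. Slc5a7, which takes up choline, had 0.411 ± 0.134 and 0.908 ± 0.40 FPKM. Slc18a3, which loads acetylcholine into vesicles and lies inside the Chat locus, had 0.346 ± 0.185 and 0.724 ± 0.158 FPKM. Chrna3 and Chrnb4, neighbours on chromosome 8, had 1.01 ± 0.406 and 0.474 ± 0.231 FPKM in untreated rats and 0.146 ± 0.0653 and 0.0568 ± 0.0305 FPKM in manipulated rats. In each of these 5 genes the groups did not overlap, and none passed limma run without the filter, with adjusted p of 0.274 to 0.372. The FPKM intervals of single libraries, as deposited, stayed apart between groups for Chrna3 and met for the other 4 genes, with Chat up to 0.610 FPKM in untreated and down to 0.536 FPKM in manipulated rats. Groups also did not overlap in other genes below the filter, and in 24.7% of all tested genes. Among them Chrna2 went the other way from Chrna3 and Chrnb4, with 0.0505 ± 0.0874 FPKM in untreated and 0.573 ± 0.369 FPKM in manipulated rats. Of the 16 genes below the filter 6 had a higher mean in manipulated rats. Ache, acetylcholinesterase, shared its row with Ufsp1, and that row had 10.9 ± 0.341 and 7.50 ± 1.32 FPKM with a limma adjusted p of 0.356. In the same libraries, thalamic and hypothalamic markers fell with a median log2 fold change of -2.37 and striatal markers had a median of 0.78, with adjusted p of 0.181 and 0.540 with an estimated correlation.

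**Figure D1:**
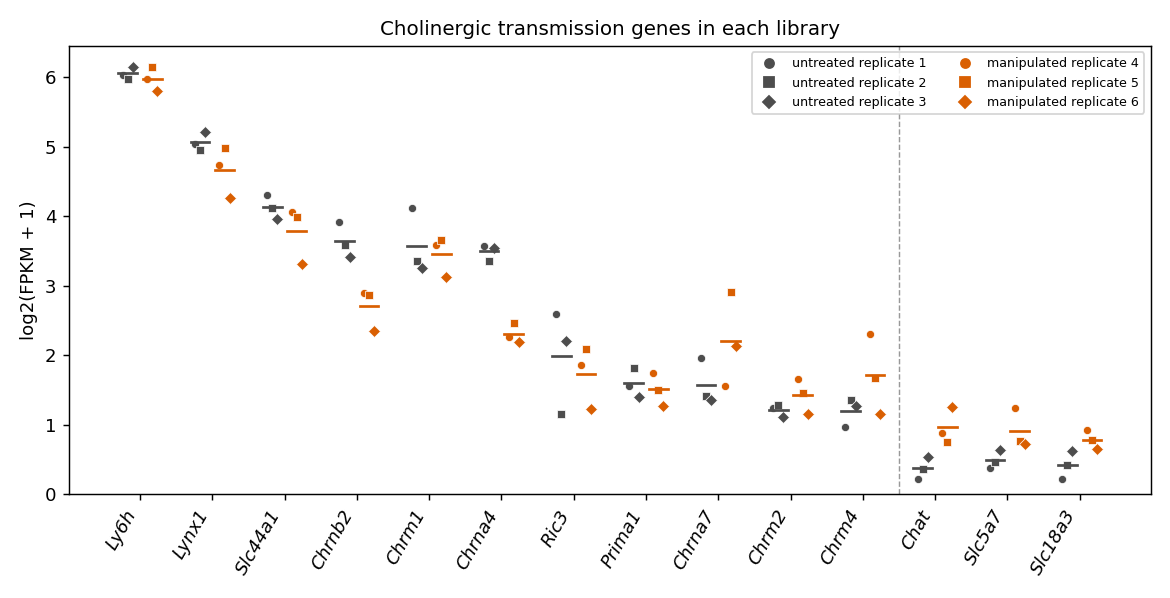
Expression of 14 cholinergic transmission genes in each library, as log2(FPKM + 1); each point is a rat, lines are group means, and genes right of the dashed line lie below the filter of 1 FPKM. The Chrna4 points of the 3 manipulated rats lie below those of the 3 untreated rats, at group means of 3.97 and 10.3 FPKM.

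Among the genes that fell by limma in manipulated rats, clone and locus names left aside, the 10 largest decreases were in Pmch, Mir3552, Prkcd, Shox2, Rasd1, Zfyve21, Slc17a6, Tcf7l2, Fosl1 and Ramp3. Of these, Pmch, Prkcd, Slc17a6 and Tcf7l2 belong to the list of thalamic and hypothalamic neurons. Pmch (chromosome 7, 28654733 to 28657522), the precursor of melanin-concentrating hormone, had 20.1, 19.2 and 30.5 FPKM in the untreated rats and 0.125, 0.0815 and 0 FPKM in the manipulated rats, with a log2 fold change of -4.48 (SE 0.23) and a limma adjusted p of 3.68e-05. Prkcd, a protein kinase of thalamic relay neurons, fell from 34.5 ± 5.74 to 4.10 ± 0.382 FPKM (SD, n = 3), a log2 fold change of -2.79 (SE 0.25). Slc17a6, the vesicular glutamate transporter of subcortical neurons, fell from 10.6 ± 0.871 to 1.18 ± 0.0881 FPKM, a log2 fold change of -2.41 (SE 0.19). The transcription factor gene Shox2 fell from 6.40 ± 1.21 to 0.165 ± 0.149 FPKM, Ramp3, a partner of calcitonin-family receptors, from 9.75 ± 0.667 to 1.38 ± 0.302 FPKM, and the transcription factor gene Tcf7l2 from 16.0 ± 7.32 to 2.17 ± 0.668 FPKM.

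The limma test passed 38 genes, 9 higher and 29 lower in manipulated rats, and 1607 genes had an unadjusted p under 0.05 where chance gives 533.8. Of the 1607 genes 156 were higher and 1451 lower, where chance gives 266.9 in each direction, while with median-ratio scaling 1202 genes had such a p, 689 of them higher and 513 lower. Groups did not overlap in 24.7% of tested genes, where chance gives 10%, and the share was 1.08% for higher and 23.7% for lower genes, while with median-ratio scaling it was 19.9% of genes, with 9.84% of genes lower. The split of the calls moved with single libraries, to 18 higher and 20 lower genes without manipulated replicate 6, 16 and 22 without manipulated replicate 4, 11 and 17 without manipulated replicate 5, and 18 and 38 without untreated replicate 2. Of the 38 genes, 6 higher and 7 lower ones have clone or locus names. Rasd1, a small G protein, had 9.28, 4.63 and 8.16 FPKM in untreated rats and 0, 0 and 1.75 FPKM in manipulated rats, and Fosl1, a member of the AP-1 family, had 6.60, 5.65 and 2.30 FPKM against 0, 0 and 0.272 FPKM. Among the increases, Mzt1, a component of microtubule nucleation, rose from 3.40 ± 0.740 to 23.6 ± 6.68 FPKM, a log2 fold change of 2.46 (SE 0.28) with an adjusted p of 0.00612. Gm22728 had 2.66, 0 and 0 FPKM in untreated rats and 12.2, 12.2 and 14.3 FPKM in manipulated rats.

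Several calls were of genes listed at 0 throughout a group, 7 of the 9 higher and 7 of the 29 lower ones, and 22 genes passed without them. Gm25117 was listed at 0 in untreated rats, where rows of another name covered its place at 24.7 FPKM or more, and at 45.9, 36.5 and 35.1 FPKM in manipulated rats. Mir3552, which lies inside the Htr2c locus on the X chromosome, had 5.40, 5.42 and 11.9 FPKM in untreated rats and was listed at 0 in manipulated rats, with such rows at 6.52 FPKM or more. That lowest value was the one of Htr2c in manipulated replicate 5, and untreated rats also had Htr2c, at 8.77, 4.24 and 4.53 FPKM. Zfyve21, a FYVE-domain protein gene, had 3.20, 4.56 and 5.47 FPKM in untreated rats and was listed at 0 in manipulated rats, where rows of another name covered its place at 5.01 FPKM or more. Of the 14 named genes that passed, 8 kept their call in every fit without 1 library. In such fits the adjusted p reached 0.254 for Gm22728, 0.266 for Rasd1, 0.154 for Tcf7l2, 0.147 for Fosl1 and 0.103 for Lef1, each of which lost its call in 4 or 5 of 6 fits, and 0.0605 for Mzt1 without untreated replicate 1. In settings with all libraries 6 of the 14 kept every call. With median-ratio scaling the adjusted p were 0.236 for Rasd1, 0.160 for Tcf7l2, 0.142 for Fosl1 and 0.0888 for Gm22728, while Lef1, Mzt1 and Mir3552 lost their calls with no filter on low values, Lef1 also with rows naming several genes kept, and Shox2 with a pseudocount of 0.01.

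Markers of thalamic and hypothalamic neurons fell together in manipulated rats. All 11 tested genes of that list were lower, with a median log2 fold change of -2.37, and 5 fell when p was adjusted over all genes and 9 when it was adjusted over the list alone. The camera adjusted p of the list was 5.00e-13 and the fry adjusted p 0.00211, while the adjusted p was 0.181 with an estimated correlation. Lef1, a transcription factor of Wnt signalling in thalamic neurons, fell from 6.27 ± 1.29 to 1.09 ± 0.381 FPKM (SD, n = 3), a log2 fold change of -1.80 (SE 0.23). Hypothalamic peptide genes, named after their values were seen, varied between rats. Hcrt had 5.29, 16.0 and 29.9 FPKM in untreated rats and 0.799, 1.85 and 2.05 FPKM in manipulated rats, while Avp had 0.811, 0.812 and 23.4 FPKM and Oxt 3.70, 3.97 and 46.5 FPKM in manipulated replicates 4, 5 and 6, against 25.8 to 31.6 FPKM and 16.2 to 40.5 FPKM in untreated rats. With median-ratio scaling the median was -2.02, and 4 genes fell over all genes and 7 over the list alone.

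Markers of striatal medium spiny neurons were higher in manipulated rats. Of 19 tested genes 17 were higher, with a median log2 fold change of 0.78, and 10 rose when p was adjusted over the list alone, although 0 passed limma over all genes and 10 had an unadjusted p under 0.05. With median-ratio scaling the median was 1.17, 16 rose over the list alone, and 1 passed over all genes, Scn4b with an adjusted p of 0.0246. The camera adjusted p was 3.62e-29, and it was 0.540 with an estimated correlation. Scn4b, a sodium channel subunit, had 5.78 ± 0.596 FPKM in untreated and 16.2 ± 3.56 FPKM in manipulated rats (SD, n = 3), and Rgs9, a regulator of dopamine receptor signalling, had 2.41 ± 0.613 and 10.6 ± 5.36 FPKM. The dopamine receptor gene Drd2 had 1.41 ± 0.735 and 4.99 ± 2.26 FPKM. These 3 genes passed over the list alone, with adjusted p of 0.0101 to 0.0224. The mean level of the list was 3.60, 3.57 and 2.57 in manipulated replicates 4, 5 and 6 and 2.44, 2.30 and 2.66 in the untreated libraries.

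**Figure D2:**
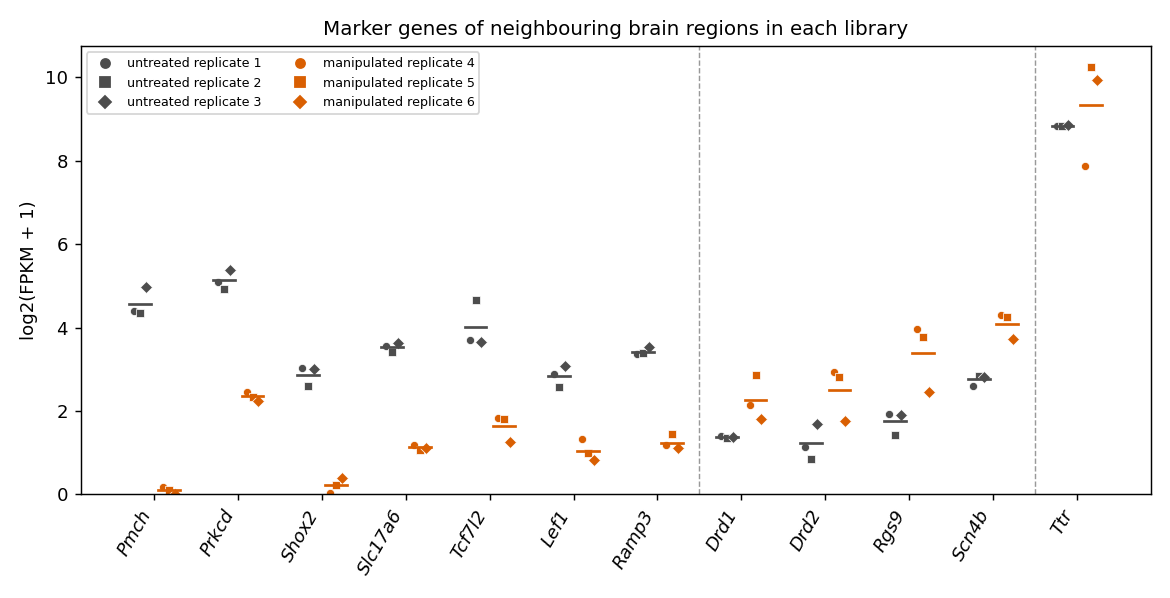
Expression of selected genes in each library as log2(FPKM + 1), with striatal genes between the dashed lines and the choroid plexus gene Ttr on the right. On the left are genes of the thalamic and hypothalamic list, and Shox2 and Ramp3, which are not on it and come from the largest decreases. Genes were drawn with their values known, so their separation is no test. Oxt and Vgf of that list, whose groups overlapped, are not drawn. Each point is a rat and lines are group means. Slc17a6 had group means of 10.6 FPKM in untreated and 1.18 FPKM in manipulated rats, and Scn4b 5.78 and 16.2 FPKM.

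Choroid plexus markers were the next highest list, with 12 of 14 tested genes higher and a median log2 fold change of 0.52. The camera adjusted p was 6.34e-13, and it was 0.674 with an estimated correlation. The mean level of the list was 1.95, 3.26 and 3.16 in manipulated replicates 4, 5 and 6 and 2.52, 2.17 and 2.07 in the untreated libraries, so that manipulated replicate 4 lay below every untreated library. The median was 0.96 without manipulated replicate 4, 0.19 without replicate 5, 0.26 without replicate 6 and 0.05 with weights per library, while it was 0.92 with median-ratio scaling. No gene of it passed limma over all genes or over the list alone, and 3 had an unadjusted p under 0.05. Kcnj13, a potassium channel gene, was listed at 0 in untreated rats and had 0, 6.47 and 7.02 FPKM in manipulated replicates 4, 5 and 6. Folr1, the folate receptor, had 2.49 ± 0.708 and 4.89 ± 1.95 FPKM (SD, n = 3), and Kl, which encodes klotho, 1.76 ± 0.688 and 4.63 ± 2.62 FPKM. Ttr, transthyretin, had 452, 452 and 462 FPKM in untreated rats and 233, 1211 and 975.8 FPKM in manipulated replicates 4, 5 and 6.

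The camera test called 5 further lists, each placed above the other tested genes, with adjusted p of 1.15e-04 for interneurons, 0.000455 for monoamine receptors, 0.00975 for deep layers, 0.000471 for olfactory bulb and 0.000479 for ependyma. With an estimated correlation the adjusted p were 0.758, 0.693, 0.924, 0.674 and 0.674 in that order, and 0 of the 35 lists passed. Cortical GABAergic interneuron markers had a median log2 fold change of 0.20 and a mean of -0.0056, so that median and mean differ in sign. In that list Cck, a neuropeptide gene, fell over the list alone from 162 ± 31.5 to 47.7 ± 7.60 FPKM (SD, n = 3) and Calb2, calretinin, from 10.7 ± 1.64 to 4.48 ± 0.475 FPKM, while Lamp5 had 7.96 ± 2.77 and 18.1 ± 5.11 FPKM and did not pass. Calb2 is also on the list of thalamic and hypothalamic neurons, which fell. As deposited 0 genes of the interneuron list rose over the list alone, and with median-ratio scaling 9 rose, Lamp5 among them, and 2 fell. Monoamine receptors had a median of -0.09 and a mean of 0.08. There Adra1b, an adrenergic receptor, fell over the list alone from 4.06 ± 0.641 to 1.39 ± 0.364 FPKM and Drd2 rose over the list alone. Deep cortical layer markers had a median of 0.04 and a mean of -0.11, and as deposited no gene passed over that list, where Pcp4 had 429 ± 121 and 184 ± 74.3 FPKM and Syt6 1.81 ± 0.269 and 3.31 ± 1.30 FPKM. Of 5 olfactory bulb genes, Lbhd2 rose over the list alone from 0.611 ± 0.218 to 2.38 ± 0.553 FPKM, while Sp9 had 0.676 ± 0.0789 and 1.75 ± 0.378 FPKM and did not pass. Ependymal markers had a median of 0.06, with Cfap126 at 0.958 ± 1.23 and 2.96 ± 1.40 FPKM and Dynlrb2 at 1.71 ± 0.510 and 2.77 ± 0.739 FPKM. With median-ratio scaling the medians were 0.19 for monoamine receptors, 0.41 for deep layers, 0.61 for olfactory bulb and 0.36 for ependyma, and 3, 2, 2 and 0 genes rose and 1, 0, 0 and 0 fell over the list alone.

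The monoamine receptor call ended with median-ratio scaling, at an adjusted p of 0.0641, and with no filter on low values, at 0.0542. Without the genes it shares with other lists its camera p was 0.0169 over 13 genes, against 6.51e-05 over 15. The deep layer call ended at a mean of at least 5 FPKM, at 0.813 over 5 tested genes, and the ependymal call ended with weights per library, at 0.155, and without manipulated replicate 6, at 0.184. In fits without 1 library, medians ran from -0.26 to 0.13 for monoamine receptors, -0.15 to 0.13 for deep layers, -0.10 to 0.58 for olfactory bulb and -0.10 to 0.18 for ependyma, and the interneuron median was 0.08 without manipulated replicate 4.

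**Figure D3:**
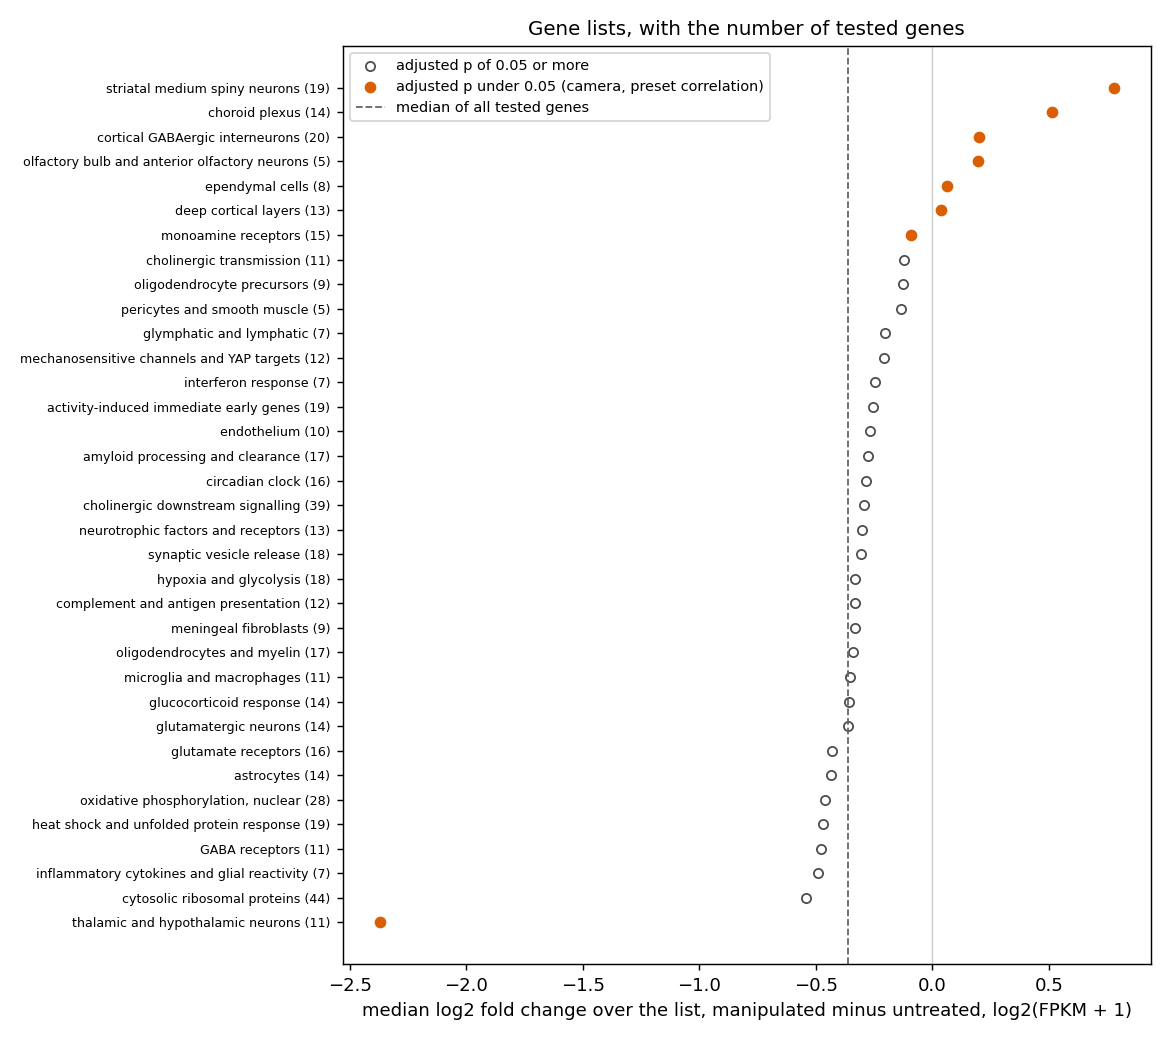
Median log2 fold change, manipulated minus untreated, of each of the 35 tested gene lists, with the number of tested genes in brackets; filled points are lists with an adjusted p under 0.05 by camera with a preset correlation, and the dashed line is the median of all tested genes at -0.36. Thalamic and hypothalamic neurons lie at -2.37 and striatal medium spiny neurons at 0.78.

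The remaining cell type lists passed no list test by camera. Among glutamatergic neuron markers Slc17a6 fell, and Neurod6 fell over the list alone from 8.44 ± 2.74 to 3.46 ± 1.47 FPKM (SD, n = 3). That list had a median log2 fold change of -0.36, the value of all genes to 2 decimals. With median-ratio scaling the median was 0.04, and over the list alone 3 genes rose and 2 fell, against 0 and 2 as deposited. Astrocyte markers had a median of -0.43, with Aldh1l1 at 3.46 ± 1.26 and 1.44 ± 0.443 FPKM, Gfap at 86.7 ± 23.1 and 48.5 ± 9.84 FPKM and Gjb6 at 8.68 ± 2.95 and 4.21 ± 0.985 FPKM. Markers of oligodendrocytes and myelin had a median of -0.34, with Aspa at 5.75 ± 2.01 and 2.53 ± 0.834 FPKM and a log2 fold change of -0.76 (SE 0.29) for Hapln2. Oligodendrocyte precursors had a median of -0.13, with Enpp6 at 1.81 ± 0.287 and 1.29 ± 0.167 FPKM, Bcas1 at 59.5 ± 14.7 and 46.3 ± 29.3 FPKM and Olig1 at 25.2 ± 4.68 and 20.1 ± 4.24 FPKM. Microglia and macrophage markers had a median of -0.35, with Laptm5 at 5.01 ± 0.373 and 3.51 ± 0.783 FPKM and P2ry12 at 5.80 ± 3.13 and 3.19 ± 0.776 FPKM. Vascular lists had medians of -0.27 for endothelium, with Cldn5 at 13.1 ± 1.99 and 9.33 ± 2.58 FPKM and a log2 fold change of -0.42 (SE 0.25) for Vwf, and -0.13 for pericytes and smooth muscle, with Acta2 at 6.97 ± 3.58 and 3.01 ± 1.00 FPKM and Myl9 at 4.49 ± 0.906 and 3.03 ± 0.794 FPKM. Meningeal fibroblasts had a median of -0.33, with Slc6a20 at 4.22 ± 3.55 and 1.50 ± 0.110 FPKM and Aldh1a2 at 1.49 ± 0.561 and 0.853 ± 0.0845 FPKM. None of these astrocyte, glial, vascular and meningeal genes passed over the list alone.

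Other pathway lists also passed no camera test. Cholinergic downstream signalling, 39 tested genes, had a median log2 fold change of -0.29 and a camera adjusted p of 0.795. Medians were -0.43 for glutamate receptors, -0.48 for GABA receptors, -0.31 for synaptic vesicle release, -0.25 for immediate early genes, -0.28 for amyloid processing and clearance, -0.49 for inflammatory cytokines and glial reactivity, -0.36 for the glucocorticoid response and -0.47 for heat shock and the unfolded protein response. The camera adjusted p of the latter was 0.114. As deposited 3 genes of the glucocorticoid response, 1 of the heat shock list and 1 of downstream signalling fell over the list alone, and with median-ratio scaling it was 0, 0 and 1, while 3 genes of downstream signalling rose. In the glymphatic and lymphatic list 1 gene fell with either scaling. With median-ratio scaling 1 GABA receptor gene rose and 2 fell over the list alone. Rises numbered 2 for glutamate receptors, 2 for immediate early genes and 1 for synaptic vesicle release. Of the 35 lists, 8 had mean levels that did not overlap between groups, all of them lower in manipulated rats, while with median-ratio scaling 9 did not overlap, 8 of them higher. The lists for mitochondrially encoded genes, histones, basal forebrain and septal neurons and blood cells had 0, 4, 4 and 2 tested genes and were not tested.

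Untreated libraries held more assembled loci without a gene name. There were 83154, 51502 and 66388 such loci in untreated and 35532, 17075 and 36520 in manipulated libraries, a ratio of group means of 0.443 with an exact permutation p of 0.1, the smallest that 3 against 3 allows. Rows that name several genes numbered 903 ± 44.7 and 788 ± 17.4 (SD, n = 3). The summed FPKM was 962217 ± 102313 and 853672 ± 59499 (SD, n = 3), with an exact permutation p of 0.3, and the 10 highest rows took 49.1% ± 4.66 and 52.2% ± 4.96 of it.

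**Figure D4:**
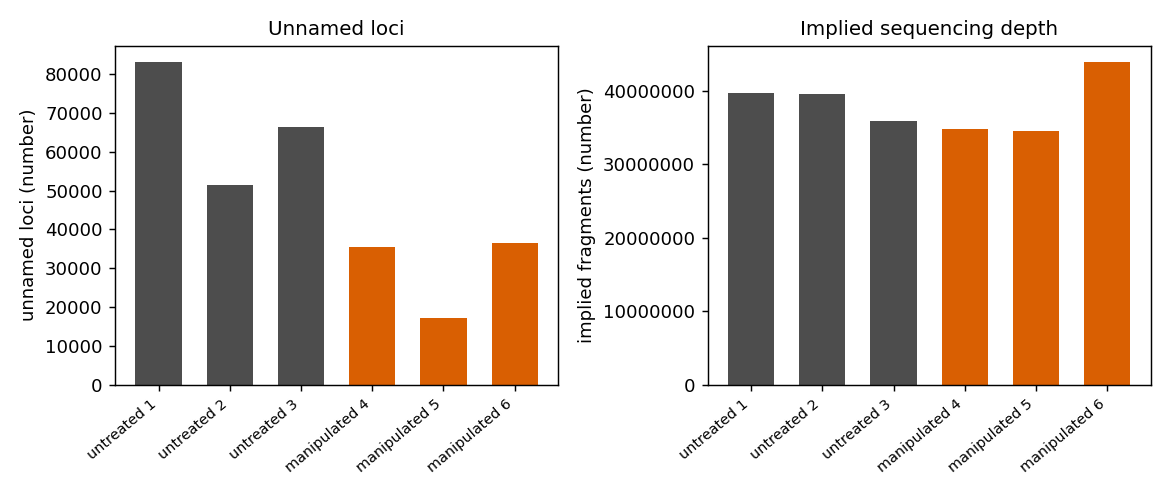
Bars give, for each library, the number of assembled loci without a gene name (left) and the implied fragment number (right). Unnamed loci numbered at least 51502 in each untreated and at most 36520 in each manipulated library, while implied fragments had group means of 3.84e+07 and 3.78e+07.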

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

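Alternatives chosen after the data were seen were keeping rows that name several genes, limiting the change in row span, leaving out genes at 0 throughout a group, and median-ratio scaling of list levels. The count of 38 genes past the adjusted p was 20 with no filter on low values (16 of them shared with the 38), 84 with a robust variance prior (35 shared), 950 with weights per library (38 shared), 431 over genes above 0 in all 6 libraries (20 shared), 24 with rows naming several genes kept (18 shared) and 22 without genes at 0 throughout a group, and 1607 genes had an unadjusted p under 0.05. The cause of these changes was not tested. It was 32 at a mean of at least 5 FPKM (16 shared), 48 over protein-coding genes (22 shared) and 37 with the change in row span limited (36 shared), where 7 lists were called. Leaving out 1 library gave 28 to 56 genes. Pseudocounts, the other scalings and the fit without a trend gave 26 to 37. The 8 called lists became 3 at a mean of at least 5 FPKM, where 23 lists could be tested, 0 with an estimated correlation and 1 with fry in a common direction. Fry placed 3 of the lists that camera put above other genes on the lower side, with adjusted p of 0.944 for monoamine receptors, 0.826 for deep cortical layers and 0.868 for interneurons, since it does not compare with other genes. The cholinergic list had a camera adjusted p of 0.813 on the opposite side at a mean of at least 5 FPKM, 0.368 with fry in a common direction, and 0.0103 with fry in either direction. Depth limits low genes: the FPKM intervals of Chat reached up to 0.610 in untreated and down to 0.536 in manipulated libraries, so that they overlapped.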

Other observations

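Tests on unnamed loci and genes listed at 0, and the bound set for the test on scaling, were chosen only after the result was seen, though median-ratio scaling itself was planned, and so were the further gene lists, whose members were written down before their values were looked at. Hippocampal markers were lower in manipulated rats in all 8 tested genes of such a list, where 87.0% of all tested genes were lower. Their median log2 fold change was -0.59 against -0.36 for all genes, a difference of -0.23 (95% bootstrap interval -1.12 to -0.04), with a camera p of 0.00523 (0.276 with an estimated correlation). The bootstrap resampled the genes of a list with the rats held fixed, so its interval holds no spread between rats. C1ql2, a synaptic protein of dentate granule cells, had 7.08 ± 4.13 FPKM in untreated and 1.23 ± 0.396 FPKM in manipulated rats (SD, n = 3), and Cabp7 had 7.76 ± 3.02 and 2.14 ± 1.03 FPKM. A habenular list had 1 tested gene and was not tested.

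Thalamic and hypothalamic markers fell while striatal markers were higher in manipulated rats, and a candidate explanation is that the slabs held different amounts of neighbouring brain regions. The tissue is labelled prefrontal cortex, yet Pmch of the thalamic and hypothalamic list had 20.1, 19.2 and 30.5 FPKM in untreated rats. In manipulated rats it had 0.125 FPKM at most. Untreated rats had no manipulation, so treatment cannot account for Pmch in their slabs, nor for Hcrt at 5.29, 16.0 and 29.9 FPKM. Those levels argue against slabs of prefrontal cortex alone in untreated rats. Among the manipulated rats, Avp had 0.811, 0.812 and 23.4 FPKM and Oxt 3.70, 3.97 and 46.5 FPKM, so levels also differed within that group. For the difference between groups, an uneven cut and an effect of treatment cannot be told apart from these values. Scaling alone is argued against, since the thalamic and hypothalamic list kept a median log2 fold change of -2.02 with median-ratio scaling. In further lists that share no gene with the first, the median lay from that of all genes by -0.49 for thalamus (95% bootstrap interval -0.75 to 0.01, camera p 0.000537) and by 0.82 for striatum (interval 0.52 to 1.16, camera p 1.74e-12). For hypothalamus it was -0.23 (interval -0.49 to -0.07, camera p 0.0837). That camera p left the second hypothalamic list undecided, although its interval lay below 0 and that for thalamus reached above 0. These intervals too resample genes and hold no spread between rats. With an estimated correlation the camera p were 0.209 for thalamus and 0.0582 for striatum. Agt, the most abundant gene of the thalamic list, had 44.9 FPKM in untreated and 18.5 FPKM in manipulated rats. It is named for its abundance, and whether it is restricted to thalamic neurons was not tested. Gnal, the most abundant gene of the striatal list in untreated rats, had 18.1 and 18.3 FPKM. An effect of manipulation on these genes stays open and untested, as do the lower Chrna4 and Chrnb2, which thalamic neurons also express. The same limit holds for every cholinergic gene above, Chat, Slc5a7 and Slc18a3 included, since none was tested apart from regional content.

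Untreated libraries held more unnamed loci, and neither depth nor unspliced RNA inside named genes accounts for that alone. The implied fragment number differed by a ratio of 1.02, untreated to manipulated, and loci outside named genes also differed, at a ratio of 0.502, manipulated to untreated. Genomic DNA could add such loci, and in male rats it would make them less dense on X than on autosomes, near 0.5. The density ratio was 0.241 to 0.307 in untreated and 0.201 to 0.349 in manipulated libraries, below that value in both groups, so the test does not separate them and DNA stays open. At 10 FPKM or more, 16 unnamed loci outside named genes were found in every untreated and no manipulated library, 3 in the reverse, and at most 6 in any of the 18 mixed sets of 3 libraries.

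Genes listed at 0 throughout a group and at 1 FPKM or more in every library of the other numbered 19, of which 15 span less than 500 bases. Several are rows of 72 bases on chromosome 8 with the same mean of 692 FPKM in manipulated rats, so the 19 need not be independent. Reads may have been given to another assembled row at the same place. A share of 0.684 of the 19 genes had such a row at 1 FPKM or more in all 3 libraries. It was 0.163 in 300 compared genes measured in every library. The share of 0.684 falls short of the 0.75 set for the test, and 4 genes had no such row in any of the 3, so this stays open. Any overlapping row counted, also that of a surrounding gene, as Htr2c for Mir3552. The 19 genes had a median span of 128 bases. The compared genes were drawn from the central range of these spans but not matched to each gene. Their share was counted in the 3 untreated libraries alone, while 9 of the 19 genes were listed at 0 in manipulated libraries. The difference in share therefore does not show that reads were moved. Of 10 splits of the 6 libraries 2 gave at least 19 such genes, the real split and 1 other, which gave 20.

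Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 38 genes past the adjusted p, with 13 the highest of the others, so no other split gave as many. The real split gave 8 lists, with 5 the highest of the others, so again no other split gave as many. Every other split still gave 3 lists or more, so camera at the preset correlation also called lists between mixed groups.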
